A study of Arabidopsis thaliana with 11 samples.

How the data were processed

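Endosperm mRNA was measured in 11 libraries of Arabidopsis thaliana, all from crosses of a Ler mother with a Col father. In experiment 1, seeds were hand-dissected 6 days after pollination and TruSeq stranded libraries were made with 15 cycles of amplification and read as pairs of 100 bases, per the labels. In experiment 2, seeds were taken 6 to 7 days after pollination and SMARTer V4 libraries were made with 12 cycles and read as single reads of 40 bases, per the labels. Each library came from seeds of crosses between multiple plants. The groups were wild type (2 libraries) and homozygous nrpd1 (3 libraries) in experiment 1, and wild type (3 libraries) and paternal nrpd1 (3 libraries) in experiment 2. The mutant allele is nrpd1a-4 per the labels, written nrpd1 here. Homozygous nrpd1 endosperm came from a mutant mother and a mutant father, and paternal nrpd1 endosperm from a wild-type mother and a mutant father. Because the kit, read length and pairing differed between experiments, each mutant was compared only with the wild type of its own experiment.

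The deposited files hold raw counts per feature for each library: the counts of all reads, and the counts of reads assigned to the Col or the Ler allele. The submitters' processing notes name cutadapt, Trim Galore, FastQC, TopHat and HTSeq and the build TAIR10, without versions or the role of each tool, and no header or label says how reads were assigned to an allele or whether strand was used. A count of a gene that overlaps another gene, or that shares sequence with a near-identical copy, is therefore uncertain. The experiment 1 tables hold 63867 features, of which 32678 have gene identifiers and 31189 transposable element identifiers. The experiment 2 tables hold 37336 features. Of these, 31912 and 37051 had an entry in the TAIR10.1 reference annotation, which was used for symbols, descriptions and chromosome positions. The 5 summary lines at the end of each experiment 2 table, worth 11.6% to 13.3% of its counts, name no gene and were left out of library sizes and tests. Another deposited file, cited per the labels by the experiment 1 samples alone, is a list of 5081 gene identifiers with no measurement (a unit of type other). It covers 3526 genes of chromosome 1 and 1555 of chromosome 2, and its name speaks of Col and nrpd1. These genes, called the listed genes, were left out of every allele comparison in experiment 1, and the text names none of them except NRPD1 unless it says so.

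Total counts per library ranged from 15926510 to 20817788 in experiment 1 and from 24845721 to 35629462 in experiment 2. Allele-assigned counts made up 17.8% to 18.4% and 7.05% to 7.82% of them. The sum of both alleles exceeded the total in 72 to 177 features of each experiment 1 library, and those counts were used as deposited. The maternal share is the percentage of a gene's allele-assigned counts that carry the Ler allele. Since the mother was always Ler and the father always Col, parent and strain cannot be told apart in any share. Wilson intervals at the 95% level and limits from 3 counts cover counting error only, because reads amplified without molecular identifiers are not independent molecules. Replicates are separate samples per the labels. The p-values of tests of single genes and of permuted libraries measure the spread between these samples. Fisher's exact tests and permutations across genes count genes, which are not independent, and do not measure that spread. Nor does camera at a preset correlation, which compares the genes of a list with the other genes.

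Total expression was tested in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr and the quasi-likelihood test, on the 5 libraries of experiment 1 and on the 6 of experiment 2. Maternal shares were tested with the same method on Ler and Col counts, with 1 term per library, an allele term and an allele by genotype term, for genes with a mean of at least 20 allele-assigned counts per library. Maternal counts alone and paternal counts alone were tested with the library sizes and factors of the total. All of these tests are two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and every adjusted p given for a gene comes from edgeR unless another tool is named. Log2 changes are mutant minus wild type and carry the standard error of the fit. CPM values are given as mean ± SD over libraries. The difference between the effects of the mutants was tested as an interaction in 1 edgeR fit of all 11 libraries. The median maternal share per library was compared with a two-sided exact permutation test. Parentally biased genes differed from 2 maternal to 1 paternal at an adjusted p under 0.05 in wild type and had a share of at least 85% or at most 50%. Overlaps of calls were tested with Fisher's exact test.

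Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, for lists with at least 3 tested genes, adjusted over the lists of a comparison. The 13 lists were maternally expressed imprinted genes, paternally expressed imprinted genes, type I MADS-box genes, RNA-directed DNA methylation, DNA methylation maintenance and removal, Polycomb repressive complex 2, endosperm growth and cellularization, seed storage and maturation, cell division, photosynthesis, heat shock response, seed coat markers and embryo markers. They overlap in a few members such as MEA. A list of all transposable element genes was not run, since the reference annotation marks none.

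Named genes followed a fixed rule. NRPD1 came first. For total expression these were, among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, the 4 largest log2 changes in each direction and then the 6 largest in each direction with a gene symbol. For maternal share the rule was the same with the change in percentage points and no CPM minimum. Members of the lists with an adjusted p under 0.05 were named too, up to 4 per list. Genes outside this rule are said to have been chosen after their values were seen. The groups, tests, lists, naming rule and most alternatives were set before the data were examined.

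Each step was tested on simulated data drawn from the real means and library sizes, with 200 genes changed. For total expression the share of changed genes recovered was 38.4% at 2-fold and 88.8% at 4-fold in the homozygous comparison (18369 genes, 18 false calls), and 0% and 10.5% in the paternal comparison (18406 genes, 5 false calls). For maternal share it was 10% and 77% in the homozygous comparison (8405 genes, 8 false calls) and 23% and 61% in the paternal comparison (7371 genes, 4 false calls). The step for parentally biased genes recovered 98.5% and 97.5% of genes at 8-fold in experiments 1 and 2, over 8405 and 7371 genes. The difference of effects recovered 0% at 2-fold and 3.78% at 4-fold for total expression (17198 genes). For maternal share it recovered 6.08% and 45.2% (5619 genes). False calls made up 12.6% and 33.3% of all calls in the homozygous and paternal comparisons of total expression. For maternal share they made up 8.42% and 4.55%, and for parentally biased genes 6.19% and 1.52%. For the difference of effects they made up 30% and 13.8%. All but 4.55% and 1.52% lay above the rate that the adjusted p threshold aims at. The 33.3% and 30% rest on 5 and 3 false calls.

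Alternatives were DESeq2 1.42.0 with its own size factors, its size factors in edgeR, no filter on low counts, a minimum of 2-fold, the sum of both alleles in place of the total, 1 fit of all libraries, the replicate number as a block, allele count minimums of 10 and 50, limma on log2 ratios with 0.5 added to each count, ratios centred per library, the listed genes kept or left out, other thresholds for biased genes, pooled shares, chromosome 1 left out, and each library left out in turn. Bootstrap intervals rest on 2000 resamples of genes, and permutation tests across genes on 100000. Shares were also averaged over windows of 1000000 bp with at least 20 genes. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. GC content and gene length were not analysed here.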

Results

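The series asked how the RNA polymerase IV small RNA pathway, and the father's copy of it, affect gene expression and the balance of the parents' alleles in endosperm, the seed tissue that feeds the embryo. NRPD1 encodes the largest subunit of RNA polymerase IV, which makes the precursors of small RNAs that direct DNA methylation. Endosperm carries 2 maternal genomes and 1 paternal, so a gene expressed equally from each copy has a maternal share of 66.7%. Experiment 1 compared 2 wild-type libraries with 3 homozygous nrpd1 libraries, and experiment 2 compared 3 wild-type libraries with 3 paternal nrpd1 libraries. Total counts were 17473822 and 19180044 in wild type and 16741818, 15926510 and 20817788 in homozygous nrpd1. In experiment 2 they were 28344044, 34911355 and 24845721 in wild type and 35629462, 34308098 and 32676580 in paternal nrpd1.

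NRPD1 itself was measured first, as the gene that the mutants carry. NRPD1 (AT1G63020) lies on chromosome 1 from 23354685 to 23362589 in TAIR10.1. It had 851 and 761 counts in wild type of experiment 1 and 451, 328 and 646 in homozygous nrpd1. Its mean was 43.6 ± 5.65 CPM (SD, n = 2) in wild type and 26.4 ± 4.38 CPM (n = 3) in homozygous nrpd1, a log2 difference of -0.72 (SE 0.16, edgeR adjusted p = 0.238) with no overlap between the libraries. In wild type, 32.2% (Wilson interval 27.4 to 37.5) and 36.0% (30.8 to 41.5) of its allele counts were maternal. In homozygous nrpd1, 0 of 191, 0 of 136 and 0 of 268 allele counts were maternal, which allows shares of up to 1.57%, 2.21% and 1.12%. NRPD1 is itself a listed gene, and the listed genes as a whole had pooled maternal shares of 7.70%, 16.6% and 4.12% in these libraries against 62.5% and 55.2% in wild type, so its allele counts there do not separate mother from father. In experiment 2, NRPD1 had 188, 462 and 298 counts in wild type and 208, 46 and 158 in paternal nrpd1, or 9.74 ± 1.15 and 3.95 ± 2.06 CPM (log2 -1.30, SE 0.46, edgeR adjusted p = 0.616, no overlap, n = 3 each). Its maternal share there was 54.0% ± 8.94 in wild type and 55.5% ± 11.7 in paternal nrpd1 (edgeR adjusted p = 1), and the log2 change of the ratio turned to -0.35 without paternal replicate 1. These shares rest on 20, 69 and 42 allele counts in wild type and 29, 2 and 21 in paternal nrpd1, too few to show an unchanged share. The counts do not tell mutant from wild-type transcripts.

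The homozygous comparison asked which genes change in total expression when both parents lack RNA polymerase IV. AT3G27980, a pectin methylesterase inhibitor family gene, rose from 0.0539 ± 0.00275 to 51.5 ± 19.3 CPM (log2 9.73, SE 0.63, adjusted p = 0.0149), and AT4G38080, a hydroxyproline-rich glycoprotein gene, rose from 0.0838 to 40.1 ± 20.4 CPM (adjusted p = 0.0487). LAC3, a laccase that oxidises phenolic compounds in cell walls, rose from 0.0819 to 14.7 ± 6.78 CPM (adjusted p = 0.0414), AT4G03540, a membrane protein gene, from 0.0260 to 5.56 ± 1.81 CPM (adjusted p = 0.0314), and PELPK1, a hydroxyproline-rich cell wall protein gene, from 0.771 ± 0.649 to 110 ± 52.9 CPM (log2 7.17, SE 0.80, adjusted p = 0.0461). Wild type held few counts of these genes, 2 of AT3G27980, 3 of AT4G38080, 3 of LAC3 and 1 of AT4G03540, so the ratios of 919 (counting interval 254 to 7595), 457 (156 to 2217), 170 (57.9 to 825) and 197 (35.1 to 7822) are loose.

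Other increases started from higher levels in wild type. LSU3, a marker of low sulfur, rose from 9.25 ± 0.670 to 62.4 ± 9.09 CPM (log2 2.75, SE 0.16, adjusted p = 0.0132). APR3 and APR1, reductases of sulfate assimilation, rose from 47.5 ± 4.77 to 140 ± 23.5 CPM (log2 1.56, SE 0.17, adjusted p = 0.0423) and from 70.2 ± 11.0 to 178 ± 8.96 CPM (log2 1.34, SE 0.12, adjusted p = 0.0266). SHM7, a serine hydroxymethyltransferase gene, rose by 1.44 (SE 0.16, adjusted p = 0.0487) and LCR40, which encodes a small secreted cysteine-rich protein, by 3.53 (SE 0.35, adjusted p = 0.0325). The genes APR2 and SULTR1;2, listed genes chosen after their values were seen, rose by 1.21 and 1.52. Among decreases, ZIP4, a zinc transporter gene, went from 220 ± 20.7 to 89.5 ± 7.84 CPM (log2 -1.30, SE 0.11, adjusted p = 0.0222), and QQS, a gene that affects starch content, from 8.32 ± 2.06 to 1.91 ± 0.121 CPM (log2 -2.11, SE 0.23, adjusted p = 0.0431). AT4G02482, a GTP-binding protein gene of the chloroplast envelope, fell by 1.85 (SE 0.17, adjusted p = 0.0266). AT4G16215, of unknown function, went from 6.30 ± 1.01 to 0.0196 CPM (adjusted p = 0.0168; 235 counts against 1, a ratio of 343 with a counting interval of 61.0 to 13601), and the transposable element feature AT1TE84330 from 5.25 ± 3.24 to 0.0196 CPM (adjusted p = 0.0457; 192 counts against 1). Of 150 transposable element features tested 1 fell and 1 rose, AT3TE47360, chosen after its values were seen, from 2 counts to 65 (log2 4.35, SE 0.50, adjusted p = 0.0487). ROS1, a DNA demethylase gene and a listed one, chosen after its values were seen, fell from 479 ± 78.8 to 146 ± 23.7 CPM (log2 -1.72, adjusted p = 0.0325).

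Of 18570 features tested, 43 rose and 19 fell, and 2177 had an unadjusted p under 0.05. DESeq2 called 365 higher and 151 lower, including all 62 of the edgeR calls. Of the 62, 31 were listed genes, 20 of them higher and 11 lower, and the other 31 were 23 higher and 8 lower. That is 0.939% of the 3302 listed genes tested and 0.203% of the other 15268 (odds ratio 4.66, interval 2.73 to 7.93, two-sided Fisher's exact p = 7.1e-09). Leaving out either wild-type library gave 0 calls, leaving out homozygous replicate 1 gave 4 higher and 2 lower, and leaving out replicate 2 or replicate 3 gave 32 and 12 or 31 and 3. Without 1 or the other wild-type library, the remaining one stands alone. Adjusting the same p-values over genes outside the list alone, a step chosen after the data were seen, left 7 higher and 1 lower. Of the genes named above AT3G27980, LSU3 and AT4G16215 still passed. The remaining calls outside the list passed only when adjusted together with the listed genes. With 1 fit of all 11 libraries the calls were 6 and 6, and AT3G27980, AT4G38080, PELPK1 and AT4G16215 still passed.

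**Figure D1:**
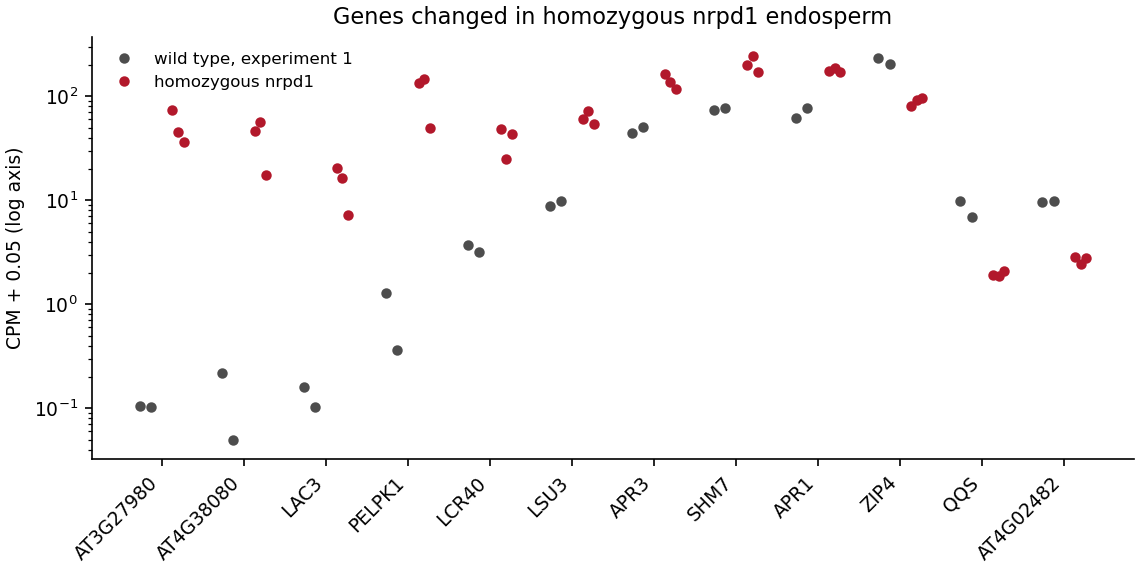
CPM plus 0.05, on a log axis, of 12 named genes in each library of experiment 1, with points for the 2 wild-type and 3 homozygous nrpd1 libraries. AT3G27980 went from 0.0539 to 51.5 CPM on average, and ZIP4 from 220 to 89.5 CPM.

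Gene lists covered the methylation pathways, imprinted genes and other seed tissues. In homozygous nrpd1, 11 of 11 genes of DNA methylation maintenance and removal had a negative log2 change (median -0.26, camera adjusted p = 0.000198), with ROS1 the 1 gene lower over all genes and 1 lower adjusted over the list alone. With an estimated correlation neither this list nor any other passed (adjusted p = 0.567 for the methylation, Polycomb and photosynthesis lists, and 0.710 for cell division and seed coat), and fry called 0 lists. RNA-directed DNA methylation genes had 18 negative and 4 positive changes (median -0.14, adjusted p = 0.00613), photosynthesis genes 15 and 4 (median -0.14, adjusted p = 0.0279), Polycomb repressive complex 2 genes 8 and 0 (median -0.18, adjusted p = 0.0371) and cell division genes 13 and 1 (median -0.17, adjusted p = 0.0371). The median of the cell division genes was 37.0 and 33.1 CPM in wild type and 35.7, 20.3 and 30.4 CPM in homozygous replicates 1, 2 and 3. Replicate 2 also stood apart in heat shock response genes (27.5 CPM, against 4.28 and 3.996 in the other mutant libraries) and in seed storage and maturation genes (2499.8 CPM, against 1144 and 1085). Its Spearman rho with the other libraries was 0.952 to 0.974, where those had 0.981 to 0.992 with one another. Seed coat markers went the other way, with 14 of 17 positive (median 0.33, adjusted p = 0.0371). Their median was 24.98 and 16.1 CPM in wild type and 57.0, 45.6 and 24.8 CPM in homozygous nrpd1, so replicate 3 did not exceed wild-type replicate 1. BAN, which acts in tannin synthesis in the seed coat and is a listed gene chosen after its values were seen, measured 17.44 ± 6.07 CPM in wild type and 157 ± 63.7 in homozygous nrpd1 (log2 3.17, adjusted p = 0.101 over all genes) and was the 1 call adjusted over the list alone. Not called were embryo markers (median -0.17, adjusted p = 0.309), heat shock response genes (0.21, 0.309), seed storage and maturation genes (0.35, 0.166) and paternally expressed imprinted genes (-0.21, 0.180, with NRPD1 itself the 1 gene lower adjusted over the list alone). Maternally expressed imprinted genes (median -0.15, mean 0.06, test upward, adjusted p = 0.867), endosperm growth genes (median -0.13, mean 0.03, adjusted p = 0.888) and type I MADS-box genes (median 0.03, test downward, adjusted p = 0.996) differed in sign between median, mean or test. SDC, an F-box gene silenced by RNA-directed methylation in leaves, was the 1 imprinted gene higher adjusted over the list alone, at 15.9 ± 5.27 CPM in wild type and 64.9 ± 11.7 in homozygous nrpd1 (log2 2.03, adjusted p = 0.0646 over all genes).

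The paternal comparison asked whether losing only the father's copy of NRPD1 changes total expression. No gene passed in edgeR, with 0 higher and 0 lower of 18901 tested, 1496 at an unadjusted p under 0.05 and a smallest adjusted p of 0.410, while DESeq2 called 5 higher and 11 lower. By camera 6 lists were called, and none of the 6 passed with an estimated correlation (adjusted p = 0.592 for heat shock and 0.427 for the others) or in fry. RNA-directed DNA methylation genes had 20 negative and 2 positive changes (median -0.83, camera adjusted p = 2.5e-06), DNA methylation maintenance and removal genes 9 and 2 (median -0.67, adjusted p = 0.000718), paternally expressed imprinted genes 10 and 2 (median -0.52, adjusted p = 0.0434) and seed storage and maturation genes 13 and 1 (median -1.29, adjusted p = 0.000358). Embryo markers had 8 negative and 4 positive changes (median -0.39, adjusted p = 0.0402), with 1 lower adjusted over the list alone, and 9 of 9 heat shock response genes were positive (median 1.76, adjusted p = 0.0108). Per library, RNA-directed DNA methylation genes had medians of 12.9, 24.3 and 22.4 CPM in wild type and 12.6, 8.54 and 9.71 in paternal nrpd1, and maintenance and removal genes 11.7, 21.3 and 16.9 CPM and 9.48, 7.82 and 13.4. Wild-type replicate 1 lay just above every mutant library in the former list and below paternal replicate 3 in the latter. Seed storage and maturation genes had 33.2, 226 and 127 CPM in wild type and 101, 25.2 and 9.01 in paternal nrpd1, with wild-type replicate 1 below paternal replicate 1. Heat shock response genes had 5.99, 1.53 and 3.32 CPM in wild type and 2.60, 41.3 and 1.98 in paternal nrpd1, so only paternal replicate 2 was high. Paternally expressed imprinted genes also parted the groups, with 3.47, 3.51 and 3.06 CPM against 2.58, 1.38 and 2.37. So did embryo markers, with 4.81, 4.997 and 5.33 CPM against 4.03, 2.41 and 3.44. With 3 libraries against 3, chance gives such a separation in 5% of cases each way. Maternally expressed imprinted genes (0.502), type I MADS-box genes (0.427), Polycomb repressive complex 2 genes (0.0703), endosperm growth genes (0.147), cell division genes (0.756), photosynthesis genes (0.234) and seed coat markers (0.410) were not called, by their camera adjusted p. ROS1 measured a log2 difference of -1.96 in paternal nrpd1 (adjusted p = 0.616).

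Whether the mutants differ in their effect on total expression was tested directly. No gene of 20078 passed in edgeR, with a smallest adjusted p of 0.0821, 1467 genes at an unadjusted p under 0.05 and 97 calls in DESeq2. Without paternal replicate 2 it called 1 gene. Kit and mutant parent change together in this contrast. Among the 17199 genes tested in both experiments, 24 and 16 were called in homozygous nrpd1 by direction, 0 and 0 in paternal nrpd1, and 0 were shared.

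The maternal share over the transcriptome asks whether the balance of the parents' genomes shifts. The median maternal share was 66.9% and 67.2% in wild type of experiment 1 and 70.5%, 75.9% and 68.8% in homozygous nrpd1, means of 67.0% ± 0.202 and 71.7% ± 3.70. The difference of 4.70 points had a two-sided exact permutation p of 0.2, the smallest that 2 against 3 libraries allow, and it was 2.64 points without homozygous replicate 2. With listed genes kept it was 2.87 points, with overlap between the groups (two-sided exact permutation p = 0.4). In experiment 2 the medians were 66.7%, 66.9% and 66.7% in wild type and 68.9%, 67.3% and 67.2% in paternal nrpd1, a difference of 1.05 points (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow). That difference was 0.515 points without paternal replicate 1. By chromosome the differences ran from 4.60 to 5.002 points in homozygous and from 0.75 to 1.35 points in paternal nrpd1. The difference between the effects was 3.65 points (two-sided permutation p = 0.355 over 200 relabellings). In homozygous nrpd1, 2639 of 8405 genes (31.4%) had every mutant library above every wild-type library and 120 (1.43%) every one below, where chance gives 10% each way. In paternal nrpd1 these were 553 of 7371 (7.50%) and 269 (3.65%), where chance gives 5% each way. These chances hold for a single gene. A shift of a whole library moves many genes together, so the counts are not evidence apart from the shift of the medians. Over all genes the median log2 change of maternal counts was 0.05 and that of paternal counts -0.27 in homozygous nrpd1, and 0.07 and 0 in paternal nrpd1. Tested by edgeR, maternal counts of 7 genes rose and of 1 fell in homozygous nrpd1, and paternal counts of 9 rose and of 6 fell.

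**Figure D2:**
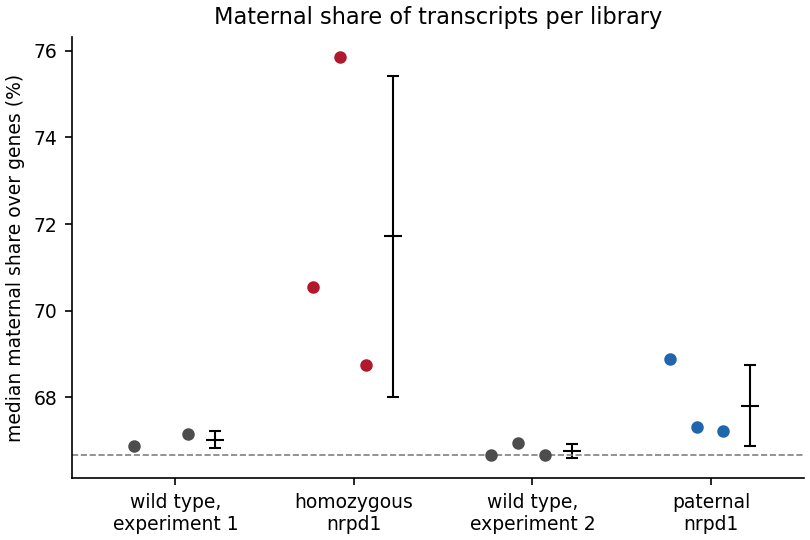
Median maternal share of genes per library, in percent, by group, with a dashed line at 66.7%, the share of maternal genomes. The homozygous nrpd1 libraries sit at 70.5%, 75.9% and 68.8%, above both wild-type libraries of experiment 1.

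Genes whose share was shifted toward 1 parent were called in wild type to follow imprinted genes, whose alleles differ by parent. Paternal bias means a share of at most 50%, so that class includes genes with about equal counts of both alleles. Of the maternally expressed imprinted genes tested, 2 of 4 were maternally biased in each experiment. Of the paternally expressed ones, 2 of 2 were paternally biased in experiment 1 and 3 of 5 in experiment 2. SUVH8, 1 of the 2 and chosen after its values were seen, had 51.5% and 38.9% in wild-type replicates 1 and 2 (mean 45.2%). In wild type of experiment 2 it measured 86.8%. Its allele counts averaged 34.6 and 21.7 per library in experiments 1 and 2. SDC and HDG9 were maternally biased in experiment 1, with shares of 96.4% and 97.6%, and HDG3, a homeobox gene expressed from the father's allele, was paternally biased at 7.16%. In homozygous nrpd1 HDG3 measured 17.0% ± 15.3, and in experiment 2 it measured 16.6% in wild type and 34.3% in paternal nrpd1 (edgeR adjusted p = 0.557). VIM5, a DNA methylation factor and a listed gene chosen after its values were seen, had a maternal share of 10.8% in wild type of experiment 2. Of seed coat markers, 9 of 10 in experiment 1 and 10 of 10 in experiment 2 were maternally biased. In all, 503 genes (5.98%) were maternally and 998 (11.9%) paternally biased in wild type of experiment 1, and 372 (5.05%) and 365 (4.95%) in experiment 2. Some 1 Mb windows outside the list had a low share in an experiment 1 library. Their genes were left out when a class was followed in the other experiment. Of the other genes called in experiment 1 and tested in experiment 2, 188 of 246 maternally biased ones (76.4%) had the same call there. For paternally biased genes it was 171 of 445 (38.4%). Of the 998 paternally biased genes, 400 lay in such windows. In those windows at the start of chromosome 5, from 1 to 4000000 in TAIR10.1, the median share was 31.9% and 25.1% in wild type of experiment 1 and 67.2% in wild type of experiment 2. Genes called paternally biased in experiment 2 had a median share of 41.3% in wild type of experiment 1 and 48.1% in homozygous nrpd1 (46.3%, 53.3% and 44.7% in replicates 1, 2 and 3), a difference of 6.84 points (two-sided exact permutation p = 0.2, the smallest possible). Those called maternally biased in experiment 2 went from 96.3% to 97.5%. In experiment 2, genes called maternally biased in experiment 1 had 97.1% in wild type and 98.8% in paternal nrpd1 (difference 1.69 points, two-sided exact permutation p = 0.1, the smallest possible), and those called paternally biased 52.5% and 54.0% (56.1%, 52.8% and 53.1% in paternal replicates 1, 2 and 3).

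**Figure D3:**
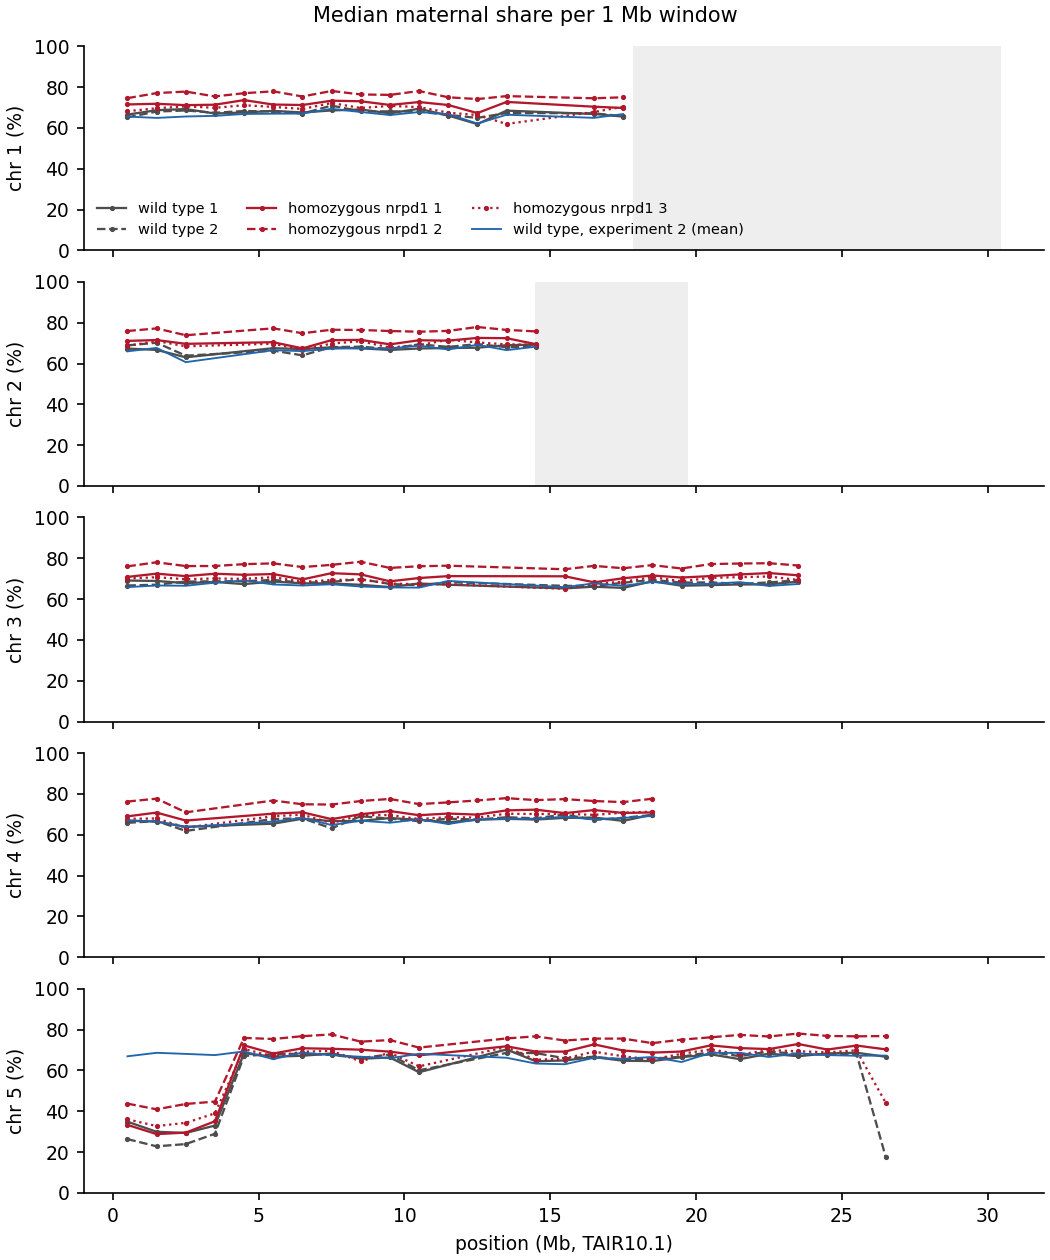
Median maternal share in percent by 1 Mb window (megabases, TAIR10.1) along the 5 chromosomes, with a line for each library of experiment 1 and for the mean of wild type in experiment 2, and grey for the listed segments. Listed genes were left out of the windows, so the lines end where the grey segments begin. The experiment 1 lines of both genotypes are low at the start of chromosome 5.

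Which single genes changed their maternal share was asked in each mutant. In homozygous nrpd1, AT1G14950, a polyketide cyclase family gene on chromosome 1, went from 51.9% ± 26.2 to 99.2% ± 0.543 (log2 ratio 5.99, SE 0.53, adjusted p = 0.00042). Its wild-type libraries stood apart at 33.3% and 70.4%, and its fitted changes were 4.84 in maternal (edgeR adjusted p = 0.607) and -1.06 in paternal counts. EXT3, an extensin of the cell wall, went from 42.8% ± 3.95 to 70.9% ± 6.30 (1.72, SE 0.27, adjusted p = 0.0331), with fitted changes of 0.98 in maternal and -0.77 in paternal counts. AT4G16190, a papain family protease gene, went from 75.3% ± 9.85 to 95.6% ± 1.41 (2.81, SE 0.40, adjusted p = 0.0144), and AT3G59480, a sugar kinase gene, from 76.1% ± 5.53 to 93.0% ± 0.740 (2.05, SE 0.25, adjusted p = 0.00375). Fitted changes in maternal and paternal counts were 2.13 and -0.71 for AT4G16190 and 1.55 and -0.52 for AT3G59480. AT2G23400, chosen after its values were seen, was the remaining higher call, at 85.4% and 96.1%. MYB115, a transcription factor gene on chromosome 5, fell from 97.8% ± 2.00 to 83.5% ± 3.47 (-3.18, SE 0.45, adjusted p = 0.0144). Its paternal counts rose by 3.14 (SE 0.51, adjusted p = 0.0164), while its maternal counts differed by -0.07. AT4G10490, an oxygenase gene, fell from 12.0% ± 2.00 to 2.22% ± 0.405 (-2.58, SE 0.28, adjusted p = 0.00212), with maternal counts down by a log2 of -2.94 (adjusted p = 0.0200). Of 8405 genes tested, 5 rose and 2 fell (647 at an unadjusted p under 0.05), and DESeq2 called 6 and 4. Without wild-type replicate 1 the calls were 126 higher and 5 lower, without replicate 2 they were 18 and 4, without homozygous replicate 1 they were 9 and 3, and without replicate 3 they were 19 and 4. Without homozygous replicate 2 they were 5 and 2, and MYB115 and AT4G16190 no longer passed (adjusted p = 0.0738 and 0.103).

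In paternal nrpd1, AT5G40700, a gene of unknown function on chromosome 5, fell from 90.9% ± 1.63 to 61.7% ± 3.86 maternal (log2 ratio -2.63, SE 0.19, adjusted p = 4.9e-06, n = 3 each), with a fitted change of 2.97 in paternal counts (SE 0.42, adjusted p = 0.1002). MYB115 fell from 96.9% ± 1.65 to 86.8% ± 1.98 (-2.46, SE 0.41, adjusted p = 0.0341), with a fitted change of 1.60 in paternal counts (adjusted p = 0.728). AT1G17200, a membrane protein gene, rose from 95.5% ± 2.44 to 99.9% ± 0.0476 (5.62, SE 0.70, adjusted p = 0.00253). SESA4, a seed storage albumin, was called higher in the fit (2.62, SE 0.43, adjusted p = 0.0341), although its share was 70.7% ± 4.24 in wild type and 94.4%, 85% and 0% in the mutant libraries. The log2 ratio of SESA4 was 0.26 without paternal replicate 1 (adjusted p = 1) and -0.0797 in limma, and the gene did not pass without wild-type replicate 2 or 3 either (adjusted p = 0.957 and 0.192). AT2G44250, a listed gene chosen after its values were seen, was the remaining higher call, at 82.4% and 99.3%. Of 7371 genes, 3 rose and 2 fell (387 at an unadjusted p under 0.05). DESeq2 called 3 and 4, as did edgeR on ratios centred per library, and limma called 0 and 0. The calls were 1 higher and 1 lower without wild-type replicate 3, 6 and 4 without paternal replicate 1, 3 and 1 without paternal replicate 2, and 2 and 1 without paternal replicate 3. MYB115 did not pass when wild-type replicate 2 or 3 or any 1 paternal library was left out (adjusted p = 0.957, 0.160, 0.0706, 0.0529 and 0.162).

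MYB115 was the 1 gene called in the same direction in both mutants among 5620 genes tested in both. Among lower calls, 0.000712 shared genes would be expected (one-sided Fisher's exact p = 0.000712 for this direction alone). Among higher calls, 0.00142 would be expected and 0 were shared. AT5G40700 measured 83.8% ± 2.40 in wild type and 63.8% ± 4.69 in homozygous nrpd1, a comparison chosen after its values were seen, with a log2 ratio of -1.56 (SE 0.26, adjusted p = 0.0539). At an adjusted p of 0.1 both genes were shared, and with DESeq2 AT2G01422, a non-coding RNA gene, was shared as well. The total expression of MYB115 differed by 0.24 in homozygous (adjusted p = 0.727) and by -0.70 in paternal nrpd1 (adjusted p = 0.616). The test of a difference between the mutants in maternal share called 0 of 7874 genes (edgeR; 382 at an unadjusted p under 0.05, smallest adjusted p 0.0976), 2 in DESeq2 and 2 in limma, and in edgeR 17 without wild-type replicate 1 of experiment 1, 2 without paternal replicate 1 and 1 without paternal replicate 3.

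**Figure D4:**
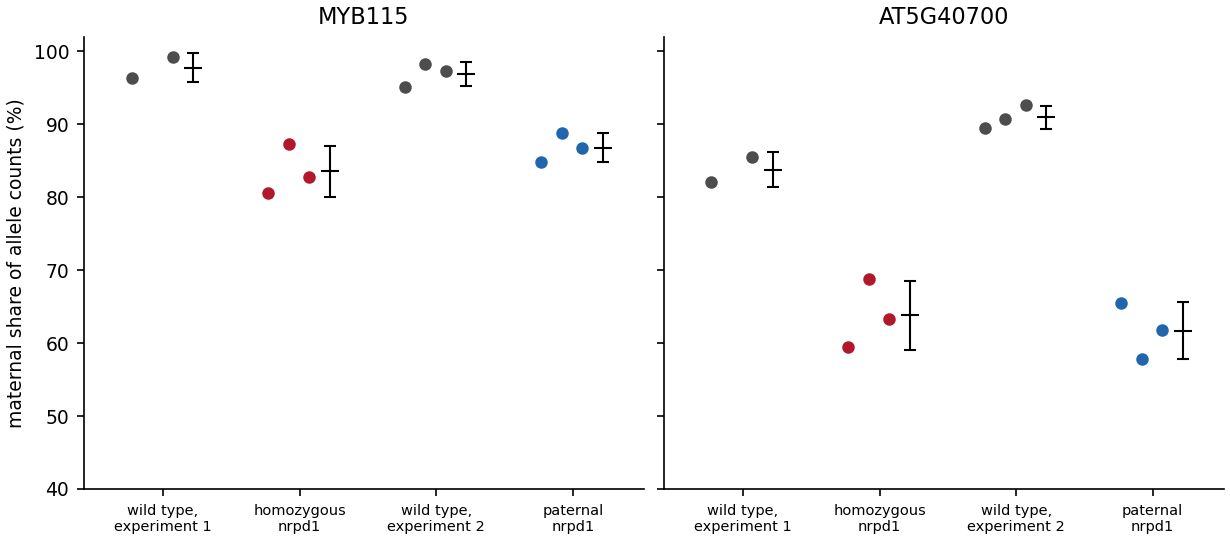
Maternal share in percent of MYB115 and AT5G40700 in each library of the 4 groups, with the mean and SD, on an axis that starts at 40%. AT5G40700 lies at 90.9% in wild type and 61.7% in paternal nrpd1 on average, and MYB115 at 97.8% and 83.5% in wild type and homozygous nrpd1.

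The same gene lists were tested by maternal share. In homozygous nrpd1 the maternal shares of maternally expressed imprinted genes (median -0.02, camera adjusted p = 0.0244) and of embryo markers (median -0.12, adjusted p = 0.0193) ranked low against the other genes, 84.1% of which had a higher mean share in the mutant. The former had 2 positive and 2 negative changes and the latter 2 and 3, and neither list passed with an estimated correlation (adjusted p = 0.872 and 0.844). WOX8, a homeobox gene of the early embryo, measured 88.2% in wild type and 68.6% in homozygous nrpd1 and was the 1 embryo marker lower adjusted over the list alone, against 0 over all genes. Of seed storage and maturation genes 2, and of heat shock response genes 2, were higher adjusted over the list alone in homozygous nrpd1, against 0 over all genes. In paternal nrpd1 no list was called by camera, and SESA4 was the 1 list member called over all genes. Adjusted over the list alone, 1 gene each was called among seed storage and maturation genes and paternally expressed imprinted genes (HDG3). VRN2 was the 1 Polycomb repressive complex 2 gene tested, so its call over the list carried no adjustment (edgeR adjusted p = 0.929 over all genes).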

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

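The tests of seed coat RNA, whole seeds and a single stretch, the odds ratio and both tests of chromosome 5 below were chosen only after the result was seen, while the correlation over listed genes and the splits of the libraries were set beforehand. The whole-seed test replaced an earlier form whose result had been seen, because many of the genes in that form had no Ler counts. The seed coat tests replaced a joint form, whose result had been seen, that took an assumed seed coat fraction as a limit.

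The listed genes were left out of the allele comparisons of experiment 1 but not of its total expression. Their pooled maternal share was 7.70% (Wilson interval 7.63 to 7.77), 16.6% (16.5 to 16.7) and 4.12% (4.07 to 4.17) in homozygous nrpd1 replicates 1, 2 and 3, against 62.5% (62.4 to 62.6) and 55.2% in wild type of experiment 1. They stand here because they are a signal in data that the share comparisons do not use. In experiment 2 the same genes had pooled shares of 64.9% to 66.6%. They span positions 17867102 to 30425192 on chromosome 1 and 14524607 to 19696821 on chromosome 2 in TAIR10.1, and NRPD1 lies in the former.

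Calls of total expression in homozygous nrpd1 were concentrated among the listed genes, 31 of the 62. The odds ratio of 4.66 (2.73 to 7.93) restates this concentration and decides nothing about its cause. Of the allele counts of listed genes, 4.12% to 16.6% were Ler in homozygous nrpd1, against 55.2% and 62.5% in wild type. The groups of this comparison therefore also differ in the alleles expressed at these genes. If Col alleles replaced Ler alleles in the mutant mother, genes whose Col allele is the more active would rise. Over 1239 listed genes the fold change followed the allele ratio of wild type in experiment 2 with a Spearman rho of 0.193 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give, across genes that are not independent), against -0.146 over 5952 other genes. The threshold set beforehand was 0.2, so Col alleles and an effect of nrpd1 that favours these genes cannot be told apart, and both may act.

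The median maternal share was higher in all 3 homozygous nrpd1 libraries than in both wild-type libraries, by 4.70 points on average, 2.64 without replicate 2, and by 2.87 points with overlap between the groups when listed genes were kept. A single stretch of the genome as the cause is argued against by the smallest difference on any chromosome, 4.60 points (4.29 to 4.91). More maternal seed coat RNA in replicate 2 than in replicate 1 is argued against by 83 maternal tissue genes, with a median log2 difference of -0.0775 (-0.21 to -0.01) where a rise is needed. From wild type to homozygous nrpd1 these genes rose by 0.19 (0.15 to 0.32), less than the 0.35 needed if seed coat gave up to 33.3% of wild-type RNA, but that fraction is assumed, so seed coat RNA stays open there. Whole seeds with no Col father could raise every maternal share, and low-share genes shifted by -0.0127 (-0.15 to 0.12, 78 genes) relative to all genes in replicate 2, which decides nothing, so this and an effect of nrpd1, which was not tested apart, stay open.

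At the start of chromosome 5, positions 1 to 4000000 in TAIR10.1, the median maternal share of 444 genes was 31.9% and 25.1% in wild type of experiment 1 and 31.1%, 43.2% and 34.8% in homozygous nrpd1. At positions 26000001 to 27000000 it was 66.7% and 17.8% in wild type and 70.3%, 76.8% and 44.2% in homozygous nrpd1, low in wild-type replicate 2 and homozygous replicate 3. A failure of allele assignment at these genes is argued against by their median of 67.1% (66.5 to 68.0, 391 genes) in wild type of experiment 2, and the same 5 windows are chosen when experiment 2 plays no part in the choice. Col DNA in mothers of experiment 1 stays open: 86.0% of the 444 genes lay below 55% in wild type, but the windows had been chosen for medians below 55%, so this decides nothing. No biological explanation was tested.

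The 10 splits of the 6 libraries of experiment 2 into 3 and 3 are too few for a share under 0.05. For total expression the real split called 0 genes and the highest other split 876. For maternal share the real split called 5 and the highest other 11. The split with 876 calls set wild-type replicate 1 and paternal replicates 2 and 3 against the other libraries, and it points to a structure of the samples other than genotype.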

How the results depend on the processing

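Leaving out low windows, and adjusting total expression over genes outside the list alone, were chosen only after the data were seen. The other alternatives were planned. Over 22 results that answer a comparison, 134 of 200 alternative values kept their direction and side of the threshold and 66 moved. Over 28 results of named genes, some named in more than 1 comparison, 226 of 340 kept theirs, 114 moved and 2 of these reversed. The cause was not tested unless the text says so.

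In total expression, DESeq2 called 365 higher and 151 lower in homozygous nrpd1, 5 and 11 in paternal nrpd1, and 97 for the difference of effects. In 1 fit of all 11 libraries the homozygous calls were 6 and 6 and the paternal calls 1 lower. With no filter on low counts the difference of effects called 1 gene. With the same p-values adjusted over genes outside the list alone, 7 rose and 1 fell in homozygous nrpd1.

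In maternal share, DESeq2 called 4 genes lower in homozygous and 4 in paternal nrpd1, 2 for the difference of effects and 3 shared. On log2 ratios in limma, 1 was lower in homozygous nrpd1, 0 higher and 0 lower in paternal nrpd1, and 2 for the difference. In limma the SESA4 log2 ratio reversed to -0.0797. With listed genes kept, 11 were higher and 721 lower in homozygous nrpd1 and 655 differed between mutants, from the low shares of the listed genes in homozygous nrpd1. With low windows left out, 30 were higher and 7 lower in homozygous nrpd1, and 612 genes were paternally biased in experiment 1. In paternal nrpd1, 4 were lower with at least 10 allele counts, 1 with at least 50, and 4 with ratios centred per library. With at least 50 allele counts, 214 genes were maternally biased in experiment 2, and with shares of at least 80% or at most 40%, 207 were paternally biased. At an adjusted p of 0.1, 2 genes were shared.

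By gene list, the 6 calls in homozygous and 6 in paternal total expression and the 2 in homozygous maternal share all became 0 with an estimated correlation, and 0 in fry.

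Leaving out 1 library gave 0 to 32 higher and 0 to 12 lower in homozygous total expression, 0 to 0 in paternal, and 0 to 1 for the difference. In maternal share it gave 5 to 126 higher and 2 to 5 lower in homozygous nrpd1, 1 to 6 and 1 to 4 in paternal nrpd1, and 0 to 17 for the difference. Maternally biased genes numbered 481 to 501 in experiment 1 and 289 to 385 in experiment 2, and paternally biased genes 825 to 965 and 285 to 309. The shift of the median share was 2.64 to 6.20 points in homozygous and 0.515 to 1.37 points in paternal nrpd1. With listed genes kept and all libraries in, the homozygous shift was 2.87 points and the groups overlapped (two-sided exact permutation p = 0.4). The NRPD1 log2 ratio in paternal nrpd1 ranged from -0.35, a reversal without paternal replicate 1, to 0.75. With 1 wild-type library left in experiment 1, the fit assumes that it varies like the other group.

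Replicate numbers did not pair the samples of experiment 2. Same-numbered libraries there had correlations of deviations of -0.528, -0.703 and 0.135, and not every library correlated best with its own number. In experiment 1 the 2 same-numbered pairs had 0.305 and 0.353, the highest value for each wild-type library. The deviations of 2 wild-type libraries mirror each other, so these values cannot show whether the numbers pair samples there. With the number as a block, total expression called 246 higher and 56 lower in homozygous nrpd1 and 0 and 0 in paternal nrpd1. With the block, maternal share called 221 and 9 and, in paternal nrpd1, 3 and 2, and the shift of the median share was 6.18 and 1.05 points.

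Depth limits the share tests, since 17.8% to 18.4% of counts in experiment 1 and 7.05% to 7.82% in experiment 2 were assigned to an allele. At the minimum of 20 allele counts 10169 genes with listed genes kept and 7371 genes were tested, against 18570 and 18901 for total expression, and leaving out listed genes took the former to 8405.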

Other observations

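The shares of maternal counts among raised genes below were compared only after the values were seen, while the tests of suberin and sulfur genes were written before the values of those genes were looked at, after related genes had been seen among the calls.

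Many genes raised in homozygous nrpd1 were expressed from the mother's allele alone. Of the 22 raised genes outside the list, 20 had at least 20 allele counts in homozygous nrpd1, and 10 of these had a maternal share of at least 99%, against 315 of 9957 tested genes (3.16%, two-sided Fisher's exact p = 1.2e-10). They include AT3G27980, with 562 of 562 allele counts maternal, AT4G38080 (732 of 732) and LAC3 (182 of 182). The sulfur genes APR1, APR3 and LSU3 were biparental, at 67.5%, 69.4% and 73.2%.

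A raised suberin program of the seed coat, where suberin is laid down, was tested as a hypothesis on suberin genes that were neither called nor listed. Their median log2 change was 3.48 and 10 of 10 were positive, where a median above 0.5 had been written down as what the hypothesis needs. ASFT, which makes suberin aromatics, measured 7.86 CPM in wild type and 87.3 in homozygous nrpd1 (log2 3.46), CYP86B1 9.63 and 43.4 CPM (2.17), and ABCG20, a suberin transporter gene, 53.5 and 146 CPM (1.45). GPAT5 had 0 counts in wild type and 191 in homozygous nrpd1, at least 43.6-fold higher by a floor of 3 counts over the group, and the median stays at 3.48 with that bound. None passed alone (edgeR adjusted p from 0.117 to 0.579), and 8 of 10 showed no overlap between groups. Chance gives 10% each way for a single gene. The 10 genes come from the same libraries and may move together, so the 8 separations are not independent evidence. KCS2 and ABCG20 overlapped, ABCG20 with 75.4 CPM in wild-type replicate 2 and 69.1 in homozygous replicate 3. ASFT varied widely between the wild-type libraries (SD 9.77 CPM). In homozygous nrpd1, 2544 of 2558 allele counts of these genes were maternal (99.5%, Wilson interval 99.1 to 99.7). The median CPM of the 10 genes was 0.531 and 2.91 in wild type and 7.92, 10.2 and 6.21 in homozygous nrpd1, while that of 83 maternal tissue genes was 36.5 and 34.8 against 48.0, 45.1 and 39.5. A suberin program further along in the seed coat of the mutant mothers, or seed coat layers carried along in different amounts, may both give this pattern, and the 2 were not tested apart. The groups also differ in the alleles expressed at the listed genes, and this was not separated from nrpd1. In paternal nrpd1, whose mother was wild type, CYP86B1, KCS20 and ABCG20 had log2 differences of -0.78, -1.74 and -0.95, and KCS2 of 1.33. None of them passed (edgeR adjusted p from 0.616 to 0.727). KCS20 measured 0.415 CPM in wild type and 0.114 in paternal nrpd1, and KCS2 0.468 and 1.15, all low. These values cannot show whether the suberin genes as a set changed there.

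A raised sulfur deficiency response was tested on 6 sulfur genes that were not among the calls. Their median log2 change in homozygous nrpd1 was 1.90, and 6 of 6 were positive, so a response of this kind may underlie the raised APR1, APR3 and LSU3. LSU1 had a log2 change of 4.57, SDI1 of 2.99, LSU2 of 2.30, SULTR4;2 of 1.502, SDI2 of 1.31 and APS3 of 0.25, none past the threshold alone (edgeR adjusted p from 0.0962 to 0.412). Such a response can follow the plants' nutrition as well as their genotype, and the data do not separate these. The groups also differ in the alleles expressed at the listed genes, APR2 and SULTR1;2 among them, and this was not separated from nrpd1. In paternal nrpd1 the log2 difference was 0.50 for LSU2, -0.61 for SDI1, -0.30 for SDI2 and -0.20 for SULTR4;2.

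AT2G01422, a non-coding RNA gene chosen after its values were seen, had a maternal share of 100% in wild type of both experiments, 38.7% ± 22.7 in homozygous nrpd1 (edgeR adjusted p = 0.162) and 34.3% ± 12.5 in paternal nrpd1 (edgeR adjusted p = 0.0556). Libraries of experiment 1 correlated with one another across genes at a Spearman rho of 0.952 to 0.992, and those of experiment 2 at 0.843 to 0.980.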
